A study of Mus musculus with 13 samples.

How the data were processed

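H3K27ac ChIP-seq was measured in 13 libraries of C57BL/6 bone marrow-derived macrophages on day 7 of differentiation, 1 library per condition. The labels describe formaldehyde-fixed chromatin, precipitation with the antibody ab4729. The cytokine experiment had libraries of untreated cells and of cells given IFNγ (100 ng/ml), IL-4 (10 ng/ml) or both for 2 h and 4 h. The knockdown experiment had scramble, shJunB and shCEBPb cells, each untreated and after 4 h of IFNγ. The labels name no shRNA for the cytokine libraries, which are called the cytokine experiment here on that ground alone.

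According to the submitters' processing notes, the authors aligned reads with Bowtie2 2.2.6 and called enriched islands with SICER 1.1, and the notes name the builds mm10 and GRCm38. Each deposited file lists the islands of 1 library. The deposited counts are raw ChIP reads and raw control reads in each island, with no normalization by the authors. The deposited p-value and FDR columns come from the authors' island calling against the control, and the deposited fold column is the ratio of ChIP reads to control reads scaled to the library. Island edges lay on a grid of 200 bp, the smallest gap between islands was 800 bp, the highest FDR 0.00999, the smallest fold 1.11 and the smallest island 18 reads. For 54791 of 54791 islands with the same coordinates in different files the control reads were equal, so a single control library served for all. Library totals were recovered from the fold column and its rounding; the smallest control total that fits is 14110230 reads, the next is 28220460, and totals were tested on simulated data, where 14 of 14 were recovered. No condition was replicated, and 0 columns were left without a sample.

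Recovered totals, in M reads, were 21.7 for untreated cells, 23.6 and 25.5 for IL-4 at 2 h and 4 h, 24.1 and 35.7 for IFNγ, 26.9 and 37.4 for both cytokines, 22.0 and 14.3 for scramble cells without and with IFNγ, 24.2 and 22.2 for shJunB, and 29.5 and 23.9 for shCEBPb. Called islands covered 176 to 206 Mb in the cytokine experiment and 218 to 244 Mb in the knockdown experiment. Exact (Clopper-Pearson) 95% intervals of the percent of reads in islands are narrower than the last printed digit. Reads have no molecular identifiers, so intervals of a fold or of a percent of reads cover counting error only. Intervals of set effects and of list medians cover the spread over regions or list members. None of them covers the variation between cultures. Only islands past the authors' threshold are listed, so a missing island is written as not called, which is no measurement of 0.

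Islands overlapping by at least 1 bp in any of the libraries were merged into 39300 union regions, with a median length of 5600 bp and a maximum of 304800 bp. ChIP reads per region were divided by median-of-ratios size factors taken over the 14311 regions called in all libraries. For regions, a library with no island was set to the 5th percentile of its reads per island. For a single gene no fold is given against a value not called. The size rule for genes, list medians and log2 ratios of genes use the same filled-in value where a library has no island. A region passed the size rule when its absolute log2 ratio was at least 1 and the higher library had at least 50 normalised reads. In simulated data the rule found 17 of 50 regions changed 2-fold, 47 of 50 changed 3-fold and 50 of 50 changed 4-fold, and passed 53 of 17743 unchanged regions. The simulation held only regions called in both libraries, at the spread of untreated shCEBPb against untreated scramble cells. These shares are therefore not error rates of the reported counts, where many regions lacked an island in a library. Between untreated scramble and untreated cytokine-experiment cells 5050 of 24451 regions (20.7%) passed. Intervals of a fold are exact binomial intervals. Set effects are the median log2 ratio of a set of regions minus the median of other regions matched on level in 20 bins. Each was set beside 10000 random sets of the same size. Their intervals are distribution-free binomial intervals of the set median over regions and take the matched median as fixed. Each of the 14 set effects, of which 6 were added after the files were seen, uses regions chosen on libraries other than the ones it compares.

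Genes were taken from the GRCm38 annotation, which gives gene spans without strand, so a gene's value is the sum over union regions touching its span or 1 kb either side, in place of the 1 kb around transcript starts that had been planned. Of 21900 protein-coding genes 14658 had a region and 7682 (52.4%) shared one with another gene. Of the genes named in the text, Gbp4 shares its region with Gbp9, Gbp5 with Gbp7, Gbp2b with Gbp2, Hmgcs1 with Nim1k, Ido1 with Adam18, Ccl5 with Taf15 and Heatr9, Nfkbiz with Nxpe3, Rsad2 with Cmpk2, Cnn3 with Slc44a3, Sfi1 with Eif4enif1, Lrrc14b with Ccdc127 and Zfp72, Arg1 with Med23, Egr2 with Ado, Mrc1 with Tmem236, Ctss with Ctsk and Arnt, Cebpg with Pepd, Stat6 with Lrp1, Nab2 and Nemp1, Junb with Prdx2, Hook2 and Rnaseh2a, and Cxcl9 and Cxcl10 with Art3 and Sdad1, so the reads count for each of them. No genome sequence was held, so the planned search for binding motifs was not made. The 24 gene lists had 389 genes, of which 388 were found: IFNγ GTPases, MHC class II, MHC class I and processing, classical activation, interferon transcription factors and regulators, interferon-stimulated antiviral genes, IL-4 alternative activation, IL-4 signalling, lipid handling and PPAR, AP-1, C/EBP, NF-kB and inflammatory genes, macrophage identity, glycolysis, cholesterol synthesis, cell cycle, housekeeping, and markers of T cells, B cells, neutrophils, dendritic cells, erythroid cells, stromal cells, and mast cells and basophils. Each list median, over distinct loci, was set beside 10000 random lists of the same size matched on level. Counts of list members higher or lower are over genes, so members with the same regions count more than once. For IFNγ at 4 h against untreated cells the 23 measured classical activation genes lay at 19 loci. The 11 MHC class II genes lay at 8 and the 16 MHC class I and processing genes at 13. Comparisons, size rule, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule named, per comparison, the 12 highest and 12 lowest protein-coding genes past the size rule, list members past it by largest absolute ratio, a set of fixed genes (among them Junb, Cebpb, Irf1, Stat6, Irf4, Ciita, Cxcl9, Socs1, Nos2, Arg1, Retnla, Chil3, Mrc1, Egr2, Ccl17 and Pparg), and the 5 highest and 5 lowest regions more than 1 kb from any gene; predicted genes were not named. The text names part of these, with those fixed genes given for the treated state alone in most knockdown comparisons, and a few further members of the lists, among them Ccl24, Ptgs1 and Hmgcs1, were repeated across comparisons after their values were seen.

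After the results were seen, IFNγ at 4 h was also fitted with edgeR's quasi-likelihood method over the 4 pairs of libraries with and without it, with the background as a block and 3 residual degrees of freedom, and each shRNA over the 6 knockdown libraries with terms for shRNA and IFNγ and 2 residual degrees of freedom. Both fits use the 14311 regions called in all libraries and p-values adjusted by Benjamini-Hochberg, and they treat a differing response between backgrounds as residual variation. Correlations run across regions, which are not independent replicates. Where compared ratios share a library, 20 simulations drew unchanged conditions against the same library. Their spread was taken from untreated shCEBPb against untreated scramble cells, so they give what sharing produces at that spread alone. Alternatives were edgeR TMM size factors, size factors from depth, background subtraction, merging over only the compared libraries, islands with FDR of at most 1e-10, a larger overlap (0.5 of the shorter island) to join islands, no filter on low counts, regions called in both libraries, reads per kb of called length, and gene spans with 5 kb or 10 kb either side; centring the ratios by their running median over 50 bins of level was added after the data were seen. Relative to the size factors used, depth scaling shifts the median log2 ratio by 0.13 for IL-4 at 2 h, 0.16 for IL-4 at 4 h, -0.11 for shCEBPb untreated against scramble, -0.15 for both cytokines against IL-4 at 2 h, 0.11 for shCEBPb with IFNγ against untreated, and 0.15 and 0.19 for scramble cells against the cytokine experiment without and with IFNγ. TMM shifts it by 0.12 for IFNγ in scramble cells, 0.12 for both cytokines at 4 h against untreated, and 0.14 for scramble cells against the cytokine experiment with IFNγ; other shifts were within 0.1. Changes are reported relative to the size factors used. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.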

Results

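Acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in 13 libraries of C57BL/6 mouse bone marrow-derived macrophages on day 7 of differentiation. A cytokine experiment of 7 libraries had untreated cells and cells given interferon-γ (IFNγ, 100 ng/ml), interleukin-4 (IL-4, 10 ng/ml) or both for 2 h or 4 h. The other 6 libraries formed a knockdown experiment with a scramble shRNA, an shRNA against Junb and an shRNA against Cebpb, each untreated and after 4 h of IFNγ. IFNγ drives the inflammatory activation of macrophages and IL-4 the alternative one, and the series asked how macrophage chromatin responds to each cytokine and to their combination. Every condition had 1 library, so no single comparison could be set against a spread between replicates. Intervals of a fold cover counting error only, and no interval given covers the variation between cultures. Tests were made only where several pairs of libraries bear on the same treatment, for IFNγ at 4 h over 4 backgrounds and for each shRNA over both states. Sequencing depth was 21.7 to 37.4 M reads in the cytokine experiment, with 77.1% to 80.0% of reads in called islands, and 14.3 to 29.5 M reads in the knockdown experiment, with 65.1% to 73.0%. The shallowest library was scramble with IFNγ, with 14.3 M reads, and the deepest was IFNγ plus IL-4 at 4 h, with 37.4 M. Islands merged into 39300 regions, of which 14311 were called in all 13 libraries. A region or gene is called higher or lower below when its normalised reads differed at least 2-fold with at least 50 normalised reads in the higher library.

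IFNγ for 4 h raised H3K27ac over the guanylate-binding proteins and immunity-related GTPases, which defend cells against intracellular pathogens. Of 18 measured members 15 were higher than in untreated cells and 0 lower, with a list median log2 ratio of 3.004, above all 10000 random lists matched on level. Gbp8 stood at 1991.9 against 77.7 normalised reads (25.6-fold), Gbp4 at 3379.4 against 165.1 and Gbp5 at 8504.7 against 531.8, while Iigp1 had 1194.0 reads and was not called in untreated cells. At 2 h the GTPase list already had a median of 2.75, with 15 of 17 measured members higher. Among genes of classical activation 17 of 23 were higher at each time and 1 lower, with medians of 1.49 at 2 h and 1.41 at 4 h. Nos2, the inducible nitric oxide synthase, was 8.83-fold higher at 4 h (95% interval 8.30 to 9.41). At 2 h Nos2 stood at 2.90-fold (2.71 to 3.11), but at a log2 ratio of -0.08 when islands were merged over only the compared libraries. The region over the chemokine genes Cxcl9 and Cxcl10, which cannot be told apart there, was 7.89-fold higher at 4 h. Cd86, a costimulatory receptor, was 6.12-fold higher at 4 h, and Ido1, which degrades tryptophan, had 373.5 reads at 4 h and was not called in untreated cells.

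Other interferon groups moved the same way at 4 h. Among interferon-stimulated antiviral genes 14 of 24 were higher at 4 h (median 1.44) and 12 at 2 h (0.98), led at 4 h by Ifi44 (11.6-fold) and Ifit3 (7.80-fold). Among interferon transcription factors and regulators 7 of 15 were higher at each time (medians 0.79 and 0.73), with Socs1, a feedback inhibitor of cytokine signalling, at 9.23-fold, Batf2 at 8.31-fold and Jak2 at 7.78-fold at 4 h. The region over Socs1 also spans 6 other protein-coding genes. Irf1, a transcription factor central to the IFNγ response, was 2.65-fold higher (2.55 to 2.75) at 4 h, while Stat6, which relays IL-4, was at 0.842-fold. MHC class II genes gave a median of 0.35 at 2 h (percentile 89.3 of the matched lists) and 1.28 at 4 h (99.9), when 5 of 11 were higher and 1, Ctss, was lower. Ciita, the master regulator of that family, was at 1.93-fold at 2 h and 3.34-fold at 4 h, and the region of H2-Ab1 and H2-Ob was 7.18-fold higher at 4 h. Of 16 genes of MHC class I and antigen processing 6 were higher at 2 h and 7 at 4 h (medians 0.76 and 0.89), led at 4 h by H2-Q4 (3.23-fold) and by the single region of Psmb8, Psmb9 and Tap1 (2.85-fold).

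Metabolic and inflammatory genes changed as well. Of 17 glycolysis genes 4 were higher at 4 h (median 0.56, percentile 98.8), with Hif1a at 6.11-fold and the glucose transporter Slc2a1 at 2.89-fold. Of 20 cholesterol synthesis genes 12 were lower at 4 h and 0 higher (median -1.40, below all matched lists), whereas at 2 h 1 was lower (median 0.11). Hmgcs1, an early enzyme of the pathway, went from 2177.1 reads in untreated cells to 1665.5 at 2 h and 189.7 at 4 h. Among lipid handling genes 3 were higher and 5 lower of 18 (median -0.60, percentile 0.80), with Lpl 5.21-fold higher and Fabp5 5.06-fold lower. NF-kB and inflammatory genes had 8 higher and 3 lower of 23 at 4 h (median 0.64), with Il6 at 811.5 reads and not called in untreated cells, and Cxcl3 11.5-fold lower in a region shared with 3 other genes. Among markers of other cell types, those of T cells had a median of 1.18 at 2 h (percentile 99.1, 4 higher and 1 lower of 7) and -0.11 at 4 h, and those of dendritic cells 0.56 at 2 h and 0.84 at 4 h (percentile 98.6, 1 higher and 2 lower of 7). The C/EBP family had a median of -0.64 over 7 members, 1 of them, Cebpg, lower. The 18 housekeeping genes had a median of 0.08.

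Over the whole genome 5254 regions were higher and 4404 lower at 2 h, of 25973 tested, and 5923 were higher and 5283 lower at 4 h, of 26935. Protein-coding genes counted 2020 higher and 1701 lower at 4 h of 13579 tested. The highest ratios at 4 h were at Bcl2l14, a BCL2-family gene (5784.6 against 64.4 reads, 89.9-fold, 68.6 to 120), the uridine phosphorylase gene Upp1 (78.3-fold), Sun3 (75.8-fold), the phospholipase A2 receptor gene Pla2r1 (55.9-fold), Spsb1 (49.4-fold), Svep1 (48.8-fold) and the interleukin-23 receptor gene Il23r (44.6-fold). Serpina3f, a serine protease inhibitor gene, had 2254.4 reads and was not called in untreated cells. The lowest were Gas6, which encodes a ligand of the TAM receptors, with 8878.2 reads in untreated cells in a region shared with Tmem255b and not called at 4 h, the kinesin gene Kif3a (2410.2 reads, not called at 4 h), Mpzl1 (56.3-fold lower) and Sh3bgrl2 (42.3-fold lower). Pparg, a lipid-sensing nuclear receptor, was 2.91-fold lower at 4 h, the mannose receptor gene Mrc1 2.89-fold lower and Irf4, a transcription factor of alternative activation, was lower, with 457.5 against 1374.5 reads. Ccl17, a chemokine gene, was 2.73-fold higher at 2 h and 3.41-fold at 4 h, Arg1 was 2.13-fold higher and Egr2 2.09-fold higher at 2 h and these stood at 1.77-fold and 1.69-fold at 4 h, and Cebpb was 2.00-fold higher at 2 h and at 1.85-fold at 4 h. Junb stood at 1.48-fold and 1.52-fold, and the IL-4 genes Retnla and Chil3 were called in none of these 3 libraries. Away from genes the highest ratio was on chromosome 8 from 46385001 to 46454600, 16.4 kb from Acsl1 and intergenic, with 8047.2 reads at 4 h and not called in untreated cells. The lowest was on chromosome 16 from 97228401 to 97253800, 57.3 kb from Dscam, with 2162.5 reads in untreated cells. That region was not called in any treated library of the cytokine experiment, those with IL-4 alone included. Its ratio therefore does not set IFNγ apart from the other treatments, which share the 1 untreated library. Of the 4 h calls 2859 higher and 3161 lower regions were called in both libraries, and per kb of called length 2142 were higher and 1836 lower, so more than 1.5 times fewer under both settings, as for each of the 9 comparisons counted here. When islands were merged over only the compared libraries, Cebpb and Egr2 at 2 h no longer passed, with log2 ratios of 0.93 and 0.90, nor did Cebpg at 4 h, with -0.68, and with 10 kb either side of genes Spsb1 did not pass at 4 h, with 0.93.

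**Figure D1:**
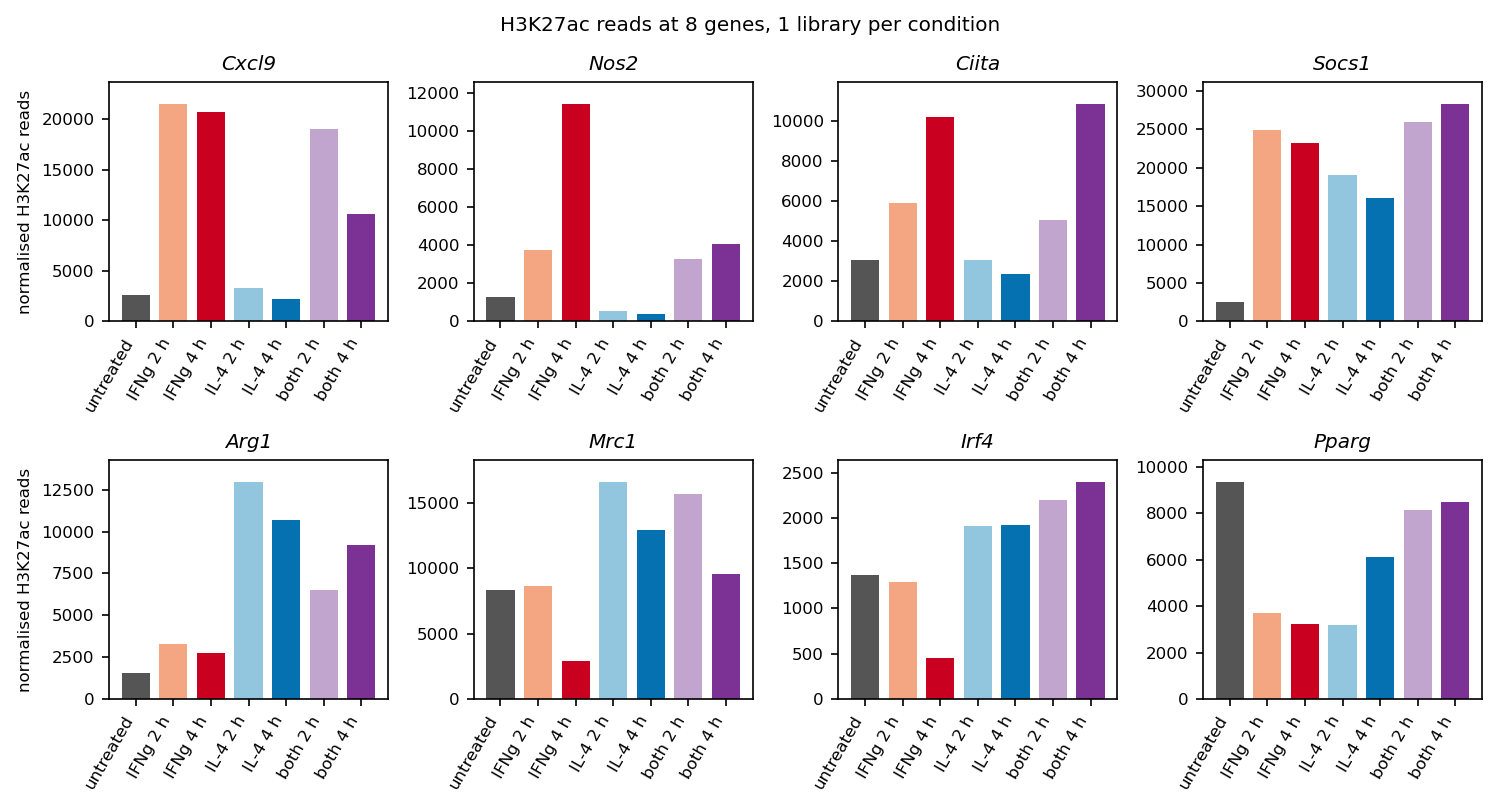
Normalised H3K27ac reads (vertical axis, linear from 0) over Cxcl9, Nos2, Ciita, Socs1, Arg1, Mrc1, Irf4 and Pparg in the 7 libraries of the cytokine experiment (horizontal axis, "both" meaning IFNγ plus IL-4); each bar is 1 library, so no error bar is drawn. Nos2 reaches 11421 reads with IFNγ at 4 h and 4078 with both cytokines, while Arg1 reaches 10684 with IL-4 at 4 h and 9212 with both.

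The scramble cells of the knockdown experiment asked whether the 4 h IFNγ response was seen again in other libraries. The GTPases again led, with 12 of 17 measured members higher and 0 lower (median 1.64, above all 10000 matched lists), among them Gbp4 (10.7-fold) and Gbp8 (7.22-fold). Classical activation genes had 12 of 22 higher (median 0.97), with Nos2 at 6.62-fold (6.22 to 7.06), the Cxcl9 region at 4.29-fold and Socs1 at 6.37-fold. Ciita was 2.91-fold higher, Mrc1 3.99-fold lower and Irf4 2.25-fold lower, while Irf1 stood at 1.61-fold and did not pass. MHC class II genes had a median of 0.39 with 1 of 11 higher, antiviral genes 0.42 with 2 of 24 higher, and cholesterol synthesis genes -0.22 (percentile 6.47) with 2 of 20 lower, among them Hmgcs1 (3.74-fold). Sun3 (26.5-fold), Upp1 (19.7-fold), F3, the tissue factor gene (15.7-fold), and Bcl2l14 (15.3-fold) had the highest ratios between called values, and Uck2 (17.4-fold lower) and Abca9 (15.5-fold lower) the lowest. Adam22 had 2294.3 reads in untreated scramble cells and was not called with IFNγ. Arg1 was 2.01-fold higher and Ccl17 had 188.1 reads where untreated scramble cells had no island, while Cebpb stood at 1.67-fold, Egr2 at 1.36-fold, Junb at 1.16-fold, Stat6 at 0.988-fold and Pparg at 0.511-fold, and Retnla and Chil3 were not called.

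In scramble cells 3707 regions were higher and 3140 lower of 25832 tested. Over the 14311 regions called everywhere, which are not independent replicates, the log2 ratios of the IFNγ response in the cytokine experiment at 4 h and in scramble cells correlated with Pearson r 0.77 and Spearman rho 0.74, and the slope of the scramble ratios on the others was 0.53. These comparisons share no library. Of the regions tested in both, 2741 were higher in both where independent lists would share 774.1, 2238 were lower in both against 588.5, and 35 and 44 went in opposite directions. Of the 5923 regions higher in the cytokine experiment 5051 could be measured in scramble cells and lay 1.29 above matched regions (1.27 to 1.32), and of the 3140 lower in scramble cells 2920 were measured in the cytokine experiment and lay at -2.04 (-2.09 to -1.99). An edgeR fit covered the 4 pairs of libraries with and without IFNγ at 4 h (cytokine experiment, scramble, shJunB and shCEBPb), with the background as a block. At an adjusted p under 0.05 the edgeR fit called 3151 regions higher and 3318 lower of the 14311, of which 1328 and 1151 changed at least 2-fold. Without shCEBPb the fit called 2141 higher and 2126 lower, and without the cytokine experiment 3314 and 3391. The scramble, shJunB and shCEBPb pairs come from 1 experiment with differing shRNAs, so the 4 pairs are not replicates of 1 condition. The untreated libraries of the experiments themselves differed, with 2196 regions higher and 2854 lower in scramble cells, and their cholesterol synthesis list had a median of -0.64. Over protein-coding genes the balance between these untreated libraries was the reverse, with 1008 higher and 581 lower in scramble cells. Reads per kb of called length gave 0.74 in place of 1.29 and -1.14 in place of -2.04, and with 10 kb either side of genes Arg1 in scramble cells had a log2 ratio of 0.98 and did not pass.

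IL-4 raised H3K27ac at its own group of genes. Of the measured alternative activation genes 23 of 35 were higher at 2 h and 1 lower (median 1.31), and 21 of 37 were higher at 4 h and 0 lower (median 1.21), above all 10000 matched lists at both times. Arg1, which converts arginine to ornithine, was 8.35-fold higher at 2 h (7.89 to 8.85) and 6.87-fold at 4 h (6.49 to 7.29). Cdh1, which encodes E-cadherin, was 41.1-fold and 36.4-fold higher in a region shared with Cdh3, and Tmem26 had 3047.2 and 4123.3 reads and Rnase2a 3309.4 and 4015.8 where untreated cells had no called island. Egr2, an early transcription factor of the IL-4 response, was 4.08-fold higher at 2 h and 2.74-fold at 4 h, and Mrc1 was 2.00-fold higher at 2 h and stood at 1.56-fold at 4 h. The chitinase-like gene Chil3 was called at 2 h and 4 h, with 212.2 and 262.3 reads, and Retnla, which encodes a secreted resistin-like protein, at 4 h alone, with 291.9.

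Inflammatory genes went both ways at 2 h of IL-4, and more of them were lower at 4 h. NF-kB and inflammatory genes had 4 higher and 2 lower of 23 at 2 h (median -0.03) and 0 higher and 4 lower at 4 h (median -0.31), and classical activation genes had 4 higher and 4 lower of 22 at 2 h. Nos2 was 2.26-fold lower at 2 h and 3.35-fold lower at 4 h, and Il12b, a subunit of interleukin-12, was 5.63-fold and 3.46-fold lower. Classical activation genes at 4 h had 3 higher and 6 lower of 22 (median -0.61, percentile 0.46), GTPases 0 higher and 5 lower of 15 (median -0.79, percentile 0.090) and antiviral genes 1 higher and 8 lower of 24 (median -0.51), among them Ifit2 (3.53-fold lower) and Rsad2 (3.25-fold lower). At 2 h these lists had medians of -0.09, 0.19 and 0.00. Socs1 was 7.56-fold higher at 2 h and 6.36-fold at 4 h, and Jak2 11.2-fold and 7.16-fold, so both were higher with either cytokine. IL-4 signalling genes had medians of 0.30 and 0.11 over 11 members, with 3 higher and 1 lower at each time, the lower one being Il13ra1, a chain of the IL-13 receptor, which did not pass when islands were merged over only the compared libraries (log2 ratios -0.18 and -0.36). Cholesterol synthesis genes had a median of 0.18 at 2 h and -0.61 at 4 h (percentile 0.040), with 5 of 20 lower at 4 h, among them Lss (2.85-fold) and Insig1 (2.77-fold). Pparg was 2.93-fold lower at 2 h and stood at 0.653-fold at 4 h. Ccl17 was 2.35-fold higher at 2 h and at 1.88-fold at 4 h, and after background subtraction it did not pass at 2 h (log2 ratio 0.97). Without passing, Cebpb stood at 1.63-fold and 1.26-fold, Irf4 at 1.39-fold at 2 h, Junb at 1.17-fold and 1.08-fold, Cxcl9 at 1.25-fold and 0.831-fold, Ciita at 1.01-fold and 0.773-fold, Irf1 at 0.872-fold and 0.860-fold and Stat6 at 0.879-fold and 0.943-fold. Markers of mast cells and basophils had medians of 1.82 at 2 h (percentile 99.9) and 0.80 at 4 h over 3 measured members.

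The highest ratios with IL-4 were at Msx3, a homeobox gene (99.8-fold at 2 h, 74.7 to 137), Scn3a, a sodium channel gene (36.4-fold and 83.7-fold), and Tarm1 (37.7-fold and 33.4-fold). Il31ra, a cytokine receptor gene in a region shared with Il6st, had 6334.1 reads at 2 h and 8994.4 at 4 h and was not called in untreated cells. The lowest called ratios were at Lrrc14b (29.3-fold lower at 2 h and 35.9-fold at 4 h), Sspn (34.3-fold lower at 4 h) and Cntnap2 (32.8-fold lower at 4 h). The intergenic region with the highest ratio at both times lay on chromosome 13 from 44665801 to 44707800, nearest to Jarid2, with 2788.1 and 2912.9 reads against 41.3. In all 3524 regions were higher and 4606 lower at 2 h of 24296 tested, and 3178 were higher and 5161 lower at 4 h of 24314. With libraries scaled by depth 4074 were higher and 4010 lower at 2 h. The lower regions were the larger share at 4 h, with 38.1% of the changed regions higher, but after the ratios were centred by their trend with level 4026 were higher, or 49.6%. Ratios at 2 h and 4 h share the untreated library and correlated with r 0.88 for IL-4 and 0.81 for IFNγ, where simulated unchanged libraries give 0.51. Their covariances were 0.817 and 0.991, against 0.0517 simulated. The simulated spread came from untreated shCEBPb against untreated scramble cells, whose log2 ratios had an SD of 0.317. Untreated scramble against untreated cytokine-experiment cells had an SD of 0.717, so the part that the shared library adds was not settled.

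Adding IL-4 to IFNγ brought IL-4 genes up and part of the inflammatory genes down. At 4 h, compared with IFNγ alone, alternative activation genes had 17 higher and 2 lower of 36 (median 0.87) and NF-kB and inflammatory genes 0 higher and 8 lower of 23 (median -0.58), above and below all 10000 matched lists. The eotaxin gene Ccl24 was 28.1-fold higher in a region shared with Ccl26 and Hip1, Ptgs1, which encodes cyclooxygenase 1, 22.9-fold, Itgb3, an integrin gene, 12.3-fold and the lectin gene Mgl2 11.2-fold. Cxcl1 and Cxcl2, neutrophil chemokines in 1 region, were 10.1-fold lower, Nfkbiz 4.67-fold, Tlr2, a receptor for bacterial lipoproteins, 3.88-fold, and Il6 3.42-fold. Irf4 was 5.25-fold higher (4.82 to 5.73), Arg1 3.34-fold, Mrc1 3.32-fold and Pparg 2.64-fold. Nos2 was 2.80-fold lower (2.72 to 2.89), Ccl5 3.99-fold lower and the region of H2-Ab1 and H2-Ob 3.40-fold lower, while Ciita stood at 1.06-fold, Irf1 at 1.00-fold, Socs1 at 1.21-fold and Cxcl9 at 0.514-fold.

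The lists that IFNγ raised had these medians at 4 h. GTPases had a median of -0.24 with 1 of 18 lower (percentile 7.98), antiviral genes -0.46 with 3 of 24 lower (percentile 0.030), classical activation genes -0.46 with 2 of 23 lower (percentile 0.18), MHC class II genes -0.19 with 4 of 11 lower (percentile 24.9) and glycolysis genes -0.20 with 0 of 17 past the size rule (percentile 13.9). MHC class I and processing genes had -0.20 with 0 of 16 past the size rule (percentile 14.2) and interferon regulators -0.13 with 0 of 15 (percentile 32.8). Cholesterol synthesis genes were higher with both cytokines than with IFNγ alone at 4 h, with 10 of 20 higher and 0 lower (median 1.01), among them Hmgcs1 (4.25-fold) and Cyp51 (3.17-fold), although against untreated cells the list with both cytokines still had a median of -0.54 with 0 higher and 1 lower. At 2 h the same comparison gave alternative activation genes a median of 0.72 (13 higher and 1 lower of 35) and NF-kB genes -0.25 (0 higher and 4 lower of 23, percentile 0.070). Antiviral genes had 0.04 (58.3), classical activation genes -0.14 (5.02) and cholesterol synthesis genes -0.11 (2.10). These medians were smaller in size than at 4 h, while GTPases at 2 h had -0.23, nearly the 4 h value, at a percentile of 0.62. At 2 h Mgl2 was 10.1-fold higher, Ccl24 9.30-fold and Pparg 2.19-fold, and Tlr2 2.51-fold lower. With 5 kb either side of genes Pparg had a log2 ratio of 0.87 and did not pass. Nos2 stood at 0.873-fold, Cxcl9 at 0.884-fold, Arg1 at 1.97-fold, Mrc1 at 1.81-fold and Irf4 at 1.70-fold at 2 h, and Ccl17 was not called with both cytokines, against 159.1 reads. At 2 h and 4 h Cebpb stood at 0.633-fold and 0.865-fold, Junb at 0.941-fold and 0.777-fold, Stat6 at 0.707-fold and 0.929-fold and Egr2 at 1.33-fold and 1.59-fold, without passing, and Retnla and Chil3 were not called.

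Over regions, 1604 were higher and 2203 lower with both cytokines than with IFNγ at 2 h, and 2627 were higher and 3963 lower at 4 h. The regions that IFNγ raised in scramble cells, which were chosen without any library of the cytokine experiment, lay at -0.44 relative to matched regions at 2 h (-0.47 to -0.41) and at -0.67 at 4 h (-0.71 to -0.63). At 2 h 23.5% of them were at least 2-fold lower than with IFNγ alone, against 6.25% of matched regions, and at 4 h 36.7% against 10.4%. Regions that IFNγ lowered went the other way, at 0.13 at 2 h and 0.48 at 4 h. On reads per kb of called length the values were -0.20 at 2 h and -0.30 at 4 h.

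Compared with IL-4 alone, IFNγ plus IL-4 brought the IFNγ genes up and took some IL-4 genes down. At 4 h GTPases had 17 of 18 higher (median 3.96) and at 2 h 15 of 17 (median 2.50), with Gbp5 25.7-fold and Gbp2b 23.2-fold higher at 4 h. Classical activation genes had 15 of 23 higher at 4 h (median 1.43) and antiviral genes 17 of 24 (median 1.35), with Nos2 10.6-fold, Cd86 9.53-fold, Cxcl9 4.89-fold, Ciita 4.59-fold and Irf1 3.08-fold higher. Retnla and Chil3 were called with IL-4 at 4 h but not with both cytokines, Chil4 was 5.87-fold lower and Itgb3 3.27-fold lower, while Ccl24 was 3.93-fold higher. With 10 kb either side of genes Retnla at 4 h had a log2 ratio of -0.89 and Pparg at 2 h 0.94, and neither passed. Arg1 stood at 0.502-fold at 2 h and 0.862-fold at 4 h, Mrc1 at 0.945-fold and 0.739-fold and Egr2 at 0.685-fold and 0.977-fold, and none of these 3 genes passed. Pparg was 2.55-fold higher at 2 h and at 1.39-fold at 4 h, and Ccl17 was not called with both cytokines at 2 h, against 136.7 reads. Socs1 stood at 1.36-fold and 1.76-fold, Irf4 at 1.15-fold and 1.25-fold, Junb at 1.19-fold and 1.09-fold, Cebpb at 0.778-fold and 1.27-fold and Stat6 at 0.785-fold and 0.829-fold. Alternative activation genes had 4 higher and 10 lower of 36 at 2 h (median -0.20, percentile 1.33) and 3 higher and 6 lower of 38 at 4 h (median 0.04). Cnn3, a calponin gene, was 121-fold higher at 4 h.

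Over regions 4614 were higher and 3493 lower at 2 h, and 4954 were higher and 3272 lower at 4 h. Regions chosen as higher with IL-4 at 4 h lay at -0.81 at 2 h (-0.86 to -0.77), with 40.0% at least 2-fold lower against 9.73% of matched regions, and those chosen at 2 h lay at -0.51 at 4 h (-0.55 to -0.47), with 31.8% against 9.81%. Those chosen as lower with IL-4 lay at 0.50 at 2 h and 0.11 at 4 h. On reads per kb of called length the higher sets lay at -0.42 and -0.24, and over regions called in both libraries the second lay at -0.34.

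**Figure D2:**
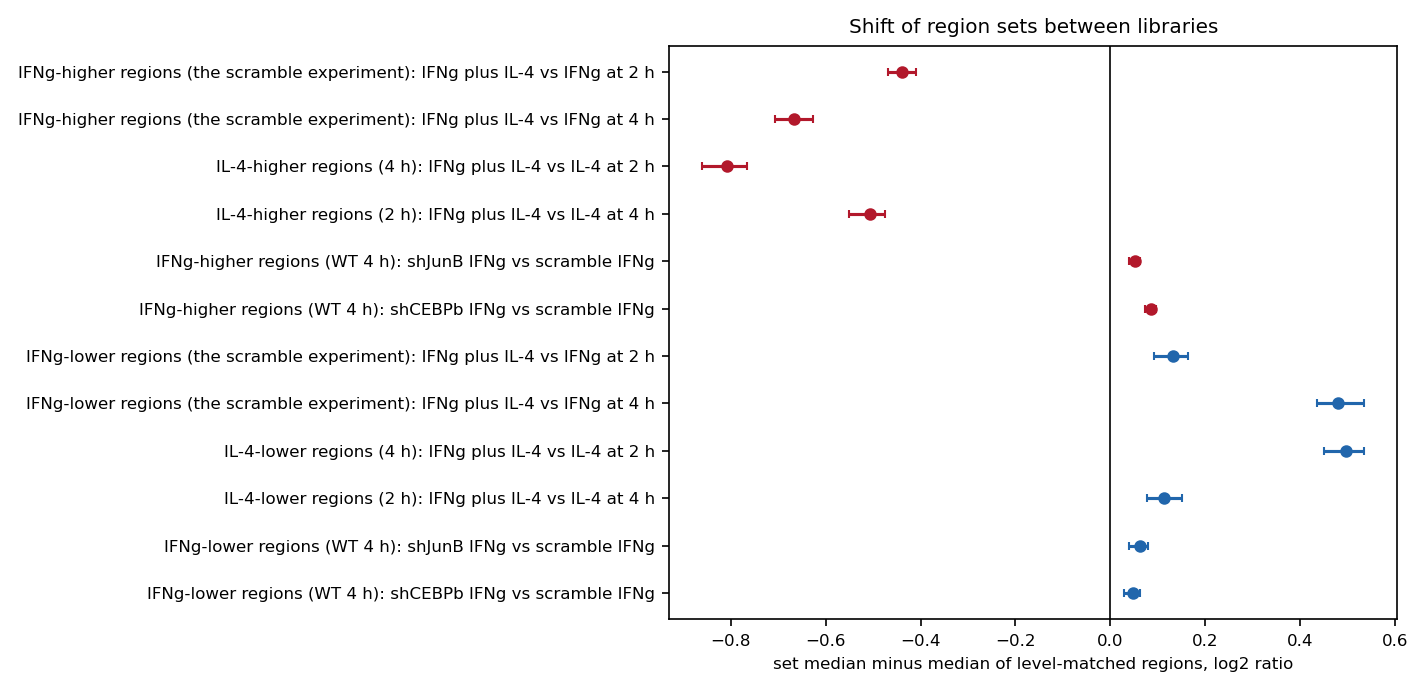
Shift of region sets between libraries: the horizontal axis is the median log2 ratio of the set minus that of regions matched on level. Bars are 95% distribution-free binomial intervals of the set median over regions. Red points are sets chosen as higher and blue points sets chosen as lower in the libraries named in parentheses. The 4 sets raised by a single cytokine lie between -0.81 and -0.44 when the other cytokine is added, and those raised by IFNγ lie at 0.05 and 0.09 with the shRNAs.

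The targeted genes were examined first in the knockdown experiment. Junb, an AP-1 subunit, had 6271.7 normalised reads in untreated shJunB cells and 7061.3 with IFNγ, against 6232.3 and 7233.9 in scramble cells and 6333.8 and 7818.8 in shCEBPb cells. Cebpb, a C/EBP transcription factor, had 7743.7 reads in untreated shCEBPb cells and 12202.4 with IFNγ, against 7564.8 and 12629.1 in scramble cells and 6865.2 and 12119.7 in shJunB cells. In the cytokine experiment Junb had 6330.8 reads in untreated cells, 7427.7 and 6863.8 with IL-4 at 2 h and 4 h, 9397.1 and 9642.4 with IFNγ and 8842.2 and 7489.8 with both, and Cebpb 5681.2, 9253.8 and 7163.1, 11368.7 and 10483.9, and 7198.0 and 9065.2. An shRNA acts on the transcript, so H3K27ac at the targeted gene does not check a knockdown and these values neither bear out nor contradict the labels. The AP-1 family had medians of 0.00 in untreated and 0.06 in IFNγ-treated shJunB cells, and the C/EBP family -0.04 and -0.05 in shCEBPb cells.

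In shJunB cells without cytokine the GTPases had a median of -0.38, lower than 99.9% of matched lists, although 1 of 17, Iigp1, passed as lower (3.05-fold). T cell markers, with a median of -0.40 over 5 members (percentile 1.76), and cell cycle genes, with -0.19 (1.27), also lay low in that comparison. With IFNγ the GTPase list had a median of 0.25 (percentile 99.97) and 0 of 17 passed, and the MHC class II list 0.26 (99.75). In untreated cells the MHC class II list had a median of -0.15 (4.48), with 2 of 11 lower. The C-type lectin gene Mgl2 was 4.18-fold lower in untreated cells and the region of H2-Ab1 and H2-Ob 2.18-fold lower. With IFNγ, Flt3, a growth factor receptor gene of progenitors and dendritic cells, was 4.03-fold higher, the matrix protease gene Mmp9 5.73-fold, the netrin gene Ntn1 7.35-fold and Grap 6.15-fold, and Wnt6 was lower, with 49.3 against 590.6 reads. Mmp9 was higher with shCEBPb as well, against the same scramble library. Ntrk2, a neurotrophin receptor gene, was lower in both states, 6.47-fold in untreated cells and not called against 549.7 reads with IFNγ. Ccl17, a chemokine gene, was higher in both, with 115.7 reads in untreated cells where scramble had no island and at 2.38-fold with IFNγ. The highest ratios in untreated cells were at Nubpl (6.87-fold), Mgam, a maltase gene (6.39-fold), and Fam167a (6.28-fold), and the lowest at Plekhg5 (8.19-fold lower), Ntrk2 and Mnd1 (6.04-fold lower). With IFNγ, Nos2 stood at 1.02-fold, Cxcl9 at 1.05-fold, Ciita at 1.37-fold, Mrc1 at 1.35-fold, Pparg at 1.29-fold, Irf4 at 1.26-fold, Irf1 at 1.11-fold, Socs1 at 1.05-fold, Egr2 at 0.938-fold, Stat6 at 0.936-fold and Arg1 at 0.805-fold. The dendritic cell marker list with IFNγ had a median of 0.25 (percentile 98.8), with 2 of 7 higher, Flt3 and Bcl11a, and the other 5 not past the size rule, and in untreated cells the list median was -0.23.

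In total 1308 regions were higher and 972 lower in untreated shJunB cells of 24318 tested, and 1112 were higher and 700 lower with IFNγ of 24648. Over protein-coding genes the balance turned, with 147 higher and 257 lower in untreated cells and 147 and 200 with IFNγ. The ratios in the untreated and treated states, which share no library, correlated with r 0.41 over regions (rho 0.36), with 229 regions higher in both against 36.4 for independent lists and 106 lower in both against 16.2. Regions that IFNγ raised in the cytokine experiment lay at 0.05 with shJunB (0.04 to 0.06) and those it lowered at 0.06 (0.04 to 0.08), and the IFNγ responses of scramble and shJunB cells correlated with r 0.85. An edgeR fit over the 6 knockdown libraries, with terms for shRNA and IFNγ, called 0 of 14311 regions for shJunB at an adjusted p under 0.05, with 2290 at an unadjusted p under 0.05 where 715.6 are expected by chance. When islands were merged over only the compared libraries H2-Ab1 did not pass in untreated cells (log2 ratio -0.59), nor did Ccl17 after background subtraction (0.59). On reads per kb of called length the IFNγ-raised set lay at 0.01, and the counts turned to 104 higher and 223 lower in untreated cells and 102 higher and 237 lower with IFNγ. Background subtraction also turned the untreated counts, to 1581 higher and 1657 lower, and gave 1367 higher and 1120 lower with IFNγ.

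In shCEBPb cells few genes of the lists passed the size rule. Without cytokine Iigp1 was 2.02-fold lower and Rrm2, a subunit of ribonucleotide reductase, was not called where scramble had 190.2 reads, while Ccl17 had 132.4 reads where scramble had no island. With IFNγ, Ptgs1 was 2.78-fold higher, the calgranulin gene S100a8 2.84-fold higher and Rnase2a 3.56-fold lower. The GTPases had medians of -0.15 without and 0.28 with IFNγ (percentiles 3.25 and 100.0) and MHC class II genes 0.03 and 0.30, with 0 of 11 past the size rule in both states. The highest ratios in untreated cells were at Ace, the angiotensin-converting enzyme gene (5.35-fold, 4.15 to 6.99), Slc28a1 (5.17-fold) and Tmem163 (5.07-fold), and the lowest called ones at Cacnb2, a calcium channel gene (5.96-fold lower), and Sema6d (4.25-fold lower). With IFNγ, Mmp9 was 6.38-fold higher and Padi1, in a region shared with Padi3, 7.29-fold lower (5.84 to 9.17), while Arg1 stood at 0.624-fold, Nos2 at 1.07-fold, Ciita at 1.29-fold, Mrc1 at 1.27-fold, Pparg at 1.24-fold, Irf4 at 1.20-fold, Irf1 at 1.16-fold, Cxcl9 at 1.07-fold, Stat6 at 0.992-fold and Egr2 at 0.970-fold. Retnla and Chil3 were not called in any library of the knockdown experiment. Mmp9 and the GTPase and MHC class II lists with IFNγ, and Iigp1 and Ccl17 without it, lay the same way in shJunB cells. Both shRNAs are set against the same scramble libraries, so these changes cannot be credited to 1 shRNA. Sfi1 was not called in untreated shCEBPb cells against 694.9 reads in scramble and had 593.4 reads with IFNγ where scramble had no island. After background subtraction Iigp1 (log2 ratio -0.97), Ccl17 (0.88) and Rrm2 (-1.08, on fewer reads) did not pass without cytokine, nor did Sema6d (-0.42) with 10 kb either side of genes. The ratios of Ccl17 and Rrm2 set the library with no island to its 5th percentile.

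In total 975 regions were higher and 475 lower in untreated shCEBPb cells of 24572 tested, and 800 were higher and 478 lower with IFNγ of 24169. In untreated cells 67.2% of the changed regions were higher, 53.9% when libraries were scaled by depth, and 43.4% on reads per kb of called length, with 92 higher and 120 lower; with IFNγ the latter gave 110 and 153, and background subtraction 1051 higher and 793 lower. The fit over the knockdown libraries called 0 of 14311 regions for shCEBPb, with edgeR, and 1167 at an unadjusted p under 0.05. The ratios without and with IFNγ correlated with r 0.16 over regions, with 76 higher in both against 18.9 for independent lists. The comparisons of the 2 shRNAs share their scramble library and correlated with r 0.62 without and 0.33 with IFNγ, where simulated unchanged libraries give 0.50 and 0.51. Their covariances were 0.0824 and 0.0403, against 0.0511 and 0.0535 simulated. The simulated spread was itself taken from untreated shCEBPb against untreated scramble cells, so these values cannot decide what sharing the library adds. The regions that IFNγ raised lay at 0.09 with shCEBPb (0.07 to 0.10), those it lowered at 0.05 (0.03 to 0.06), and the raised ones at 0.02 on reads per kb of called length, and the IFNγ responses of scramble and shCEBPb cells correlated with r 0.86.

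**Figure D3:**
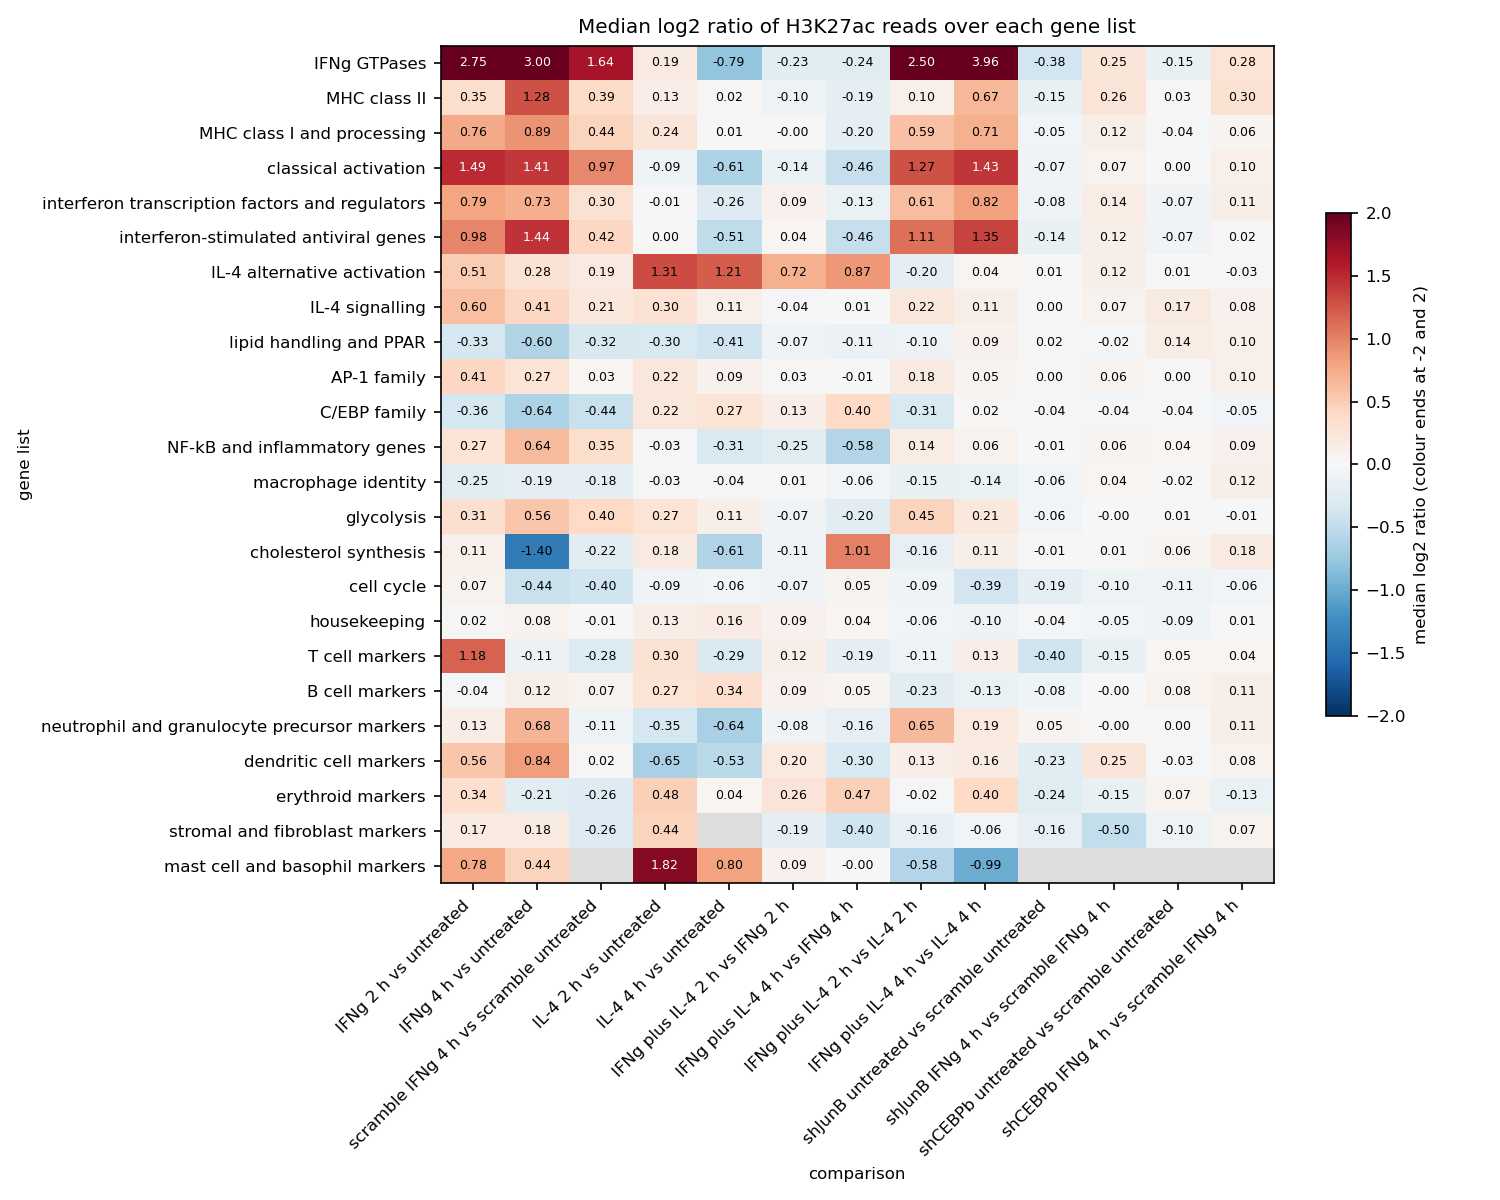
Median log2 ratio of normalised H3K27ac reads for each gene list (vertical axis) in 13 comparisons (horizontal axis), with the value in each cell, colours ending at -2 and 2, and grey where fewer than 3 loci were measured. The GTPases reach 3.004 with IFNγ at 4 h and alternative activation genes 1.31 with IL-4 at 2 h, and the cholesterol synthesis list lies at -1.40 with IFNγ at 4 h against untreated cells and at 1.01 with both cytokines against IFNγ alone.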

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

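Every test in this part was chosen after its result or the pattern was seen, except that the 4 effects of regions raised by a single cytokine were planned, and that the outcome of centring the shJunB correlation by level was not known when that test was chosen. With 1 library per condition, a difference between cultures of the same condition was not measured and stays open for each pattern.

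A difference between states drew attention to the IFNγ GTPases with shJunB: their median log2 ratio to scramble cells was -0.385 without cytokine and 0.25 with IFNγ, shCEBPb cells set against the same scramble libraries turned alike (-0.15 and 0.28), and the difference was not tested. A difference between times drew attention to cholesterol synthesis genes: with IFNγ plus IL-4 their median log2 ratio to IFNγ alone was -0.11 at 2 h and 1.01 at 4 h, and the difference was not tested.

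Regions raised by a single cytokine had less H3K27ac when the other was added. Choosing regions by their ratio cannot account for this, since sets chosen on libraries outside each comparison lay at -0.44 or below. These effects are already taken against regions matched on signal level, so a trend with level would largely cancel in them. Centring by level repeats that matching and is no separate test of such a trend. After it the set nearest 0 lay at -0.41. A loss by the same fraction at every IFNγ-raised region was not decided: of 62 regions at least 4-fold higher with IFNγ in scramble cells and little moved by IL-4 alone, 4, or 6.45% (exact interval 1.79% to 15.7%), had as much or more signal with both cytokines at 4 h, and the median was -0.90 with an SD of 0.84. An effect of the added cytokine, which the design names, stays open and was not tested against the variation between cultures.

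Cholesterol synthesis genes were lower with IFNγ at 4 h in the cytokine experiment. The untreated library alone is argued against by a median of -1.37 (bootstrap interval over members -2.61 to -0.68) between IFNγ at 4 h and at 2 h. A state shared alike by all 4 h libraries is argued against by the pair of them farthest apart. That pair, both cytokines and IFNγ, had a median of 1.01 (0.35 to 1.46), and the interval does not allow for the choice of the pair. A first form of this test, IFNγ against IL-4 at 4 h, gave -0.82 (-1.18 to -0.23). Its bound of -0.25 left that undecided, and the form was changed after that. An IFNγ effect that scales between the experiments as over all regions would give -0.75 in scramble cells, where the median was -0.22 (-0.37 to 0.13), beside -0.30 in shJunB and -0.09 in shCEBPb cells; but the list already lay at -0.64 (-0.92 to -0.38) in untreated scramble against untreated cytokine-experiment cells, with 20 of 20 members below 0, so the smaller fall may go with that lower start. The list was also lower at 4 h than at 2 h with IL-4 (-0.90, -1.28 to -0.58) and with both cytokines (-0.46, -0.86 to -0.27), and IL-4 at 4 h gave -0.61 against untreated cells, so a culture or time effect of differing size in the 4 h libraries, or an IFNγ effect that depends on the experiment or on the level before treatment, may be involved, and the design does not part them.

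Changes with an shRNA were alike without and with IFNγ for shJunB more than for shCEBPb. For shJunB the correlation of 0.41 over regions stands above 0.24, the higher of the correlations between the shRNAs that share no library, the other being 0.00, and after centring by level it was 0.41, so neither a difference of the scramble libraries nor a trend with level accounts for all of it. For shCEBPb the correlation of 0.16 lies between those crossed values, which is consistent with a difference of the scramble libraries. An effect of the shJunB construct or a difference between cell batches carrying it may remain for shJunB, and a fit over both states called 0 regions for either shRNA at an adjusted p under 0.05 (edgeR, with 2290 for shJunB and 1167 for shCEBPb at an unadjusted p under 0.05).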

How the results depend on the processing

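Centring by level and the fits over several pairs of libraries were chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible by replicate number because every condition had 1 library. All 420 list medians checked kept their direction, as did all 140 values of set effects, of which 44 lay outside the interval of the reported one. The list medians checked were only those already large and extreme among their matched lists, so small medians, which turn more easily, were left out. Of 196 counts of regions 156 stayed within 1.5 times. Of 1448 values of named genes 1420 stayed past the size rule and 27 no longer passed. The other turned: merging islands over only the compared libraries gave Nos2 with IFNγ at 2 h a log2 ratio of -0.0785, and the cause was not tested. Leaving out each background in turn, the IFNγ fit called 2106 to 3314 regions higher and 2126 to 3391 lower, with fewer libraries in each. The motif search was not run. A 2-fold change lies at the size rule itself, and 17 of 50 simulated ones passed; what depth adds to this was not varied.

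Requiring an island in both libraries, which leaves fewer regions, gave 2739 higher and 2853 lower for IFNγ at 2 h, 2859 and 3161 at 4 h, 1954 and 2956 for IL-4 at 2 h, 1731 and 3390 at 4 h, 2071 and 1892 for IFNγ in scramble cells, 698 and 556 for shJunB without and 623 and 391 with IFNγ, and 548 and 193 for shCEBPb without and 476 and 250 with IFNγ. Reads per kb of called length gave, in the same order, 1848 and 1641, 2142 and 1836, 894 and 1813, 947 and 1345, 761 and 665, 104 and 223, 102 and 237, 92 and 120, and 110 and 153; the cause was not tested. Background subtraction gave 1657 lower regions for shJunB without IFNγ (against 1581 higher), 1120 with IFNγ and 793 for shCEBPb with IFNγ, and the cause was not tested.

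Set effects moved as follows with background subtraction, with islands in both libraries and with reads per kb, and the cause was not tested. Regions raised by IFNγ gave -0.48, -0.36 and -0.20 with both cytokines against IFNγ at 2 h, and -0.75, -0.58 and -0.30 at 4 h. Regions raised by IL-4 gave -0.92, -0.54 and -0.42 against IL-4 at 2 h, and -0.58, -0.34 and -0.24 at 4 h, with -0.75 and -0.47 under depth scaling. Regions raised by IFNγ in the cytokine experiment gave 1.51, 0.98 and 0.74 in scramble cells, 0.0758, 0.0295 and 0.0108 with shJunB, and 0.0544 and 0.0175 with shCEBPb under the last 2 settings. Regions lowered in scramble cells gave -2.33, -1.66 and -1.14 in the cytokine experiment, and -2.14 under TMM.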

Other observations

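The correlation of IL-4 responses with the IFNγ response of scramble cells and the fit over 4 backgrounds with its splits were chosen after the data were seen. Between 2 h and 4 h of IFNγ the MHC class II genes moved further, with 5 of 11 higher at 4 h than at 2 h and 0 lower (median 1.06), while the GTPases had a median of 0.16 with 0 of 18 past the size rule. Nos2 was 3.04-fold higher at 4 h than at 2 h (2.93 to 3.16) and Bcl2l14 13.8-fold, while Cxcl9 stood at 0.966-fold and Socs1 at 0.933-fold. Mrc1 was 3.02-fold lower and Irf4 2.83-fold lower at 4 h than at 2 h. Macc1 had 3482.1 reads at 4 h and was not called at 2 h, and the P-selectin gene Selp, in a region shared with F5, was 14.6-fold lower at 4 h. Cholesterol synthesis genes had 10 of 20 lower (median -1.37) and T cell markers 3 of 7 lower (median -0.70). In all 3256 regions were higher and 3338 lower at 4 h than at 2 h.

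Further lists had these medians with IFNγ at 2 h and 4 h. IL-4 signalling genes had 0.60 and 0.41, the AP-1 family 0.41 and 0.27, macrophage identity genes -0.25 and -0.19 and cell cycle genes 0.07 and -0.44, the last with a percentile of 1.12. Alternative activation genes had 0.51 at 2 h with 10 higher and 4 lower of 33, and 0.28 at 4 h with 9 higher and 7 lower of 35. Of the markers of other cell types, those of B cells had -0.04 and 0.12, neutrophils 0.13 and 0.68, erythroid cells 0.34 and -0.21, stromal cells 0.17 and 0.18, and mast cells and basophils 0.78 and 0.44, the last over 3 measured members. With IL-4 the dendritic cell markers had -0.65 and -0.53 and neutrophil markers -0.35 and -0.64.

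The IFNγ and IL-4 responses were also set side by side in libraries with none shared, taking IFNγ from scramble cells. Across regions, r was 0.37 with IL-4 at 2 h and 0.26 at 4 h. At 4 h 1443 regions were lower in both, where independent lists would share 628, 659 were higher in both against 241, and 407 were higher with IFNγ and lower with IL-4 against 486. Within the cytokine experiment, where both responses share the untreated library, Socs1 and Jak2 are among the genes higher with either cytokine. Kif3a had 2410.2 reads in those untreated cells. It was not called with IFNγ at 2 h or 4 h or with IL-4 at 2 h. These gene values therefore do not come from libraries with none shared.

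The fit of IFNγ at 4 h over 4 backgrounds was repeated for the other splits of its 8 libraries that part the libraries of every background. Of these 8 splits 1, the real one, called 6469 regions and the highest of the others called 0, and 8 splits are too few for a share under 0.05. In the other splits the IFNγ difference of the swapped pairs enters the residual variation. Their count of 0 therefore does not show how many regions would be called without any IFNγ effect.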
